A study of Arabidopsis thaliana with 6 samples.

How the data were processed

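Root RNA of Arabidopsis thaliana seedlings was measured on 6 Affymetrix ATH1 arrays, 2 each for Col-0, rsl4-1 and 35S::RSL4. Per the labels' protocols, seedlings grew on vertical plates of MS medium at pH 5.7 with 1% sucrose, in continuous light at 25 °C, to growth stage 3.2, and RNA was labelled with biotin by in vitro transcription from the 3' end. The deposited intensity values are MAS5 signals on a linear scale, made by the authors with MAS5 and GCOS per the submitters' processing notes, with versions not given in the sources used here. The mean signal without the lowest and highest 2% was 100.01 on every array, so the authors' scaling of each array was kept. MAS5 uses no model across arrays and is noisy for dim probe sets, and global scaling cannot see a change of total RNA.

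Of 22810 probe sets, 64 controls were left out, and the remaining 22746 were filtered to the 14170 above the array's own 40th percentile on at least 2 of the 6 arrays, which left 8576 below the filter. The annotation table gave 1 gene for 13513 probe sets, several for 503 and did not list 8730, which are unnamed here. Of the one-gene probe sets, 13436 were matched by gene number to the RefSeq gene table of assembly TAIR10.1, from which names and the order of neighbouring loci were taken. No coordinates are given, since no build is named with the values. Of the tested probe sets 7669 (54.1%) had 1 gene.

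Genotypes were taken from the sample titles. The log2 signals were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with all 6 arrays in one fit (3 residual and 13.2 prior degrees of freedom). Adjusted p-values are limma's, two-sided, with Benjamini-Hochberg adjustment over the probe sets of each comparison and a threshold of 0.05. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333, so no permutation test of single genes was used. The median SE of a log2 change was 0.166. A fold is 2 to the power of the log2 change. Where a probe set was below the 40th percentile on both arrays of 1 genotype, the fold is given as at least the bright group's level over, per array, the higher of that percentile and the dim signal. No fold is given where both genotypes were dim.

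The test, the 19 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Named were the 10 probe sets with the largest rise and the 10 with the largest fall per comparison among those called, with 1 gene and with both arrays of one genotype beyond both of the other. Up to 4 members of each list with a called member, by adjusted p, and up to 10 opposite changes, by the difference between 35S::RSL4 and rsl4-1, were named too. Where no probe set passed, the 5 with the smallest p were to be named. The lists covered root hair regulators, root hair cell wall, extensins, root hair specific genes, tip growth, epidermal patterning, class III peroxidases, markers of root cap, endodermis, vasculature, meristem and shoot tissue, iron, phosphate, auxin, ethylene, defence, heat and handling stress, and reference genes. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry.

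Comparisons that share the Col-0 arrays were set beside 100 simulated draws of unchanged groups. Tested on simulated data for 35S::RSL4 versus Col-0 with 14170 probe sets and 200 changed, the fit recovered 94% of 2-fold and 100% of 4-fold changes, and 6.54% of its calls were unchanged probe sets. Alternatives were quantile normalization, median centring, no filter, the upper part by mean signal, a 20th percentile offset, no intensity trend, only the 2 groups compared, a replicate block, a threshold of 0.1, other set tests, the mean of all probe sets of a locus, and leaving out each array. Where an array was left out, the lone array of its genotype was assumed to vary like the others. Position along the chromosomes was tested with Fisher's exact test, two-sided, over windows of 250, 500 and 1000 loci each side of RSL4, with 95% intervals, and one-sided for more calls over 78 stretches of up to 500 loci with Benjamini-Hochberg adjustment.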

Results

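The series compared root transcripts of 3 genotypes of Arabidopsis thaliana: wild-type Col-0, the rsl4-1 mutant, and 35S::RSL4 plants. RSL4 is a basic helix-loop-helix transcription factor that promotes the growth of root hairs, the tubular outgrowths of epidermal root cells. The 35S promoter of cauliflower mosaic virus drives strong expression in most plant tissues. Each genotype had 2 samples, each hybridised to its own ATH1 array, so the number of arrays limits the precision of every value. The labels do not say whether the 2 samples of a genotype were separately grown, so p-values measure only the spread between these samples, which may be technical. Signals are MAS5 signals in scaled units, and means are given ± SD with n = 2 arrays per genotype.

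The level of RSL4 itself was examined first, but no probe set was matched to RSL4 by the annotation used here, so its level was not used to check the labels. The genetic variation entry of the labels reads knock-out for rsl4-1 and also for 35S::RSL4. The samples are therefore called by the genotype in their titles. Over the 14170 tested probe sets, arrays of one genotype correlated at 0.983 to 0.986 and arrays of different genotypes at 0.957 to 0.972, across probe sets, which are not independent replicates. The first principal component held 42.6% of the variance and had both 35S::RSL4 arrays at 25.5 and 27.5, against values from -22.9 to -3.76 for the other arrays.

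The comparison of rsl4-1 with Col-0 asked which root transcripts depend on RSL4. The root hair cell wall genes EXPA7 and EXPA18, 4 of 7 measured extensins and 2 of 18 measured class III peroxidases fell in rsl4-1, and 5 peroxidases rose. AT1G30870, a class III peroxidase gene 425 annotated loci from RSL4, fell 3.47-fold, from 541 ± 77.5 to 156 ± 16.9 (log2 change -1.80, SE 0.15, adjusted p = 2.3e-06). GSTU25, a glutathione transferase of the tau class, fell 3.44-fold, from 274 ± 4.24 to 79.8 ± 6.1 (adjusted p = 4.6e-06). In the other direction hemb2, a gene of tetrapyrrole synthesis, was at least 11.6-fold higher in rsl4-1, where its signal was 258 ± 22.4 (adjusted p = 2.2e-08). It was too dim in the other genotypes to be tested without rsl4-1 replicate 1 or 2.

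Of the 3 measured members of the root hair cell wall list, which holds 13 genes, 2 fell and 1 did not pass. The expansin genes EXPA7 and EXPA18 encode wall-loosening proteins of root hairs. EXPA7 fell 1.61-fold (log2 change -0.69, SE 0.15, adjusted p = 0.017) and EXPA18 fell 1.52-fold (log2 change -0.60, SE 0.14, adjusted p = 0.02). XTH26, a xyloglucan endotransglucosylase gene, had a log2 change of -0.64 (adjusted p = 0.078). Adjusted over the list alone, 3 of the 3 were lower. The list was lower as a set (camera adjusted p = 0.000319), with adjusted p = 0.16 with an estimated correlation. The call of EXPA7 ended without Col-0 replicate 1 or 2 or rsl4-1 replicate 2 (adjusted p = 0.055, 0.21 and 0.18). That of EXPA18 ended without Col-0 replicate 1 or 2 or rsl4-1 replicate 1 or 2 (adjusted p = 0.22, 0.071, 0.055 and 0.19), and both ended with a variance model that had no intensity trend (adjusted p = 0.059 and 0.077).

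Extensins are hydroxyproline-rich structural wall proteins, and 4 of the 7 measured fell in rsl4-1 while 3 did not pass. Adjusted over the list alone, 6 were lower. AT4G08410 fell 2.4-fold, from 138 ± 3.64 to 57.6 ± 3.84 (adjusted p = 5.3e-05), and AT5G06630 fell 2.24-fold (adjusted p = 0.00036). HRGP1 fell 1.87-fold (adjusted p = 0.00048) and AT3G54580 fell 1.9-fold (adjusted p = 0.0044), a call that ended without Col-0 replicate 1 (adjusted p = 0.07) or rsl4-1 replicate 1 (adjusted p = 0.084). The extensin list was lower as a set (camera adjusted p = 1.42e-09), with adjusted p = 0.0301 with an estimated correlation. The probe sets of AT4G08410, AT5G06630, HRGP1 and AT1G23720 are of a type that can bind related transcripts, so these extensins may share signal. The counts and set tests of extensins take them as separate genes.

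Class III peroxidases, which act on hydrogen peroxide in the cell wall, went both ways: 5 of the 18 measured rose, 2 fell and 11 did not pass. Adjusted over the list alone, 9 were higher and 4 lower. Beside AT1G30870, AT1G34510 fell 2.41-fold, from 251 ± 12.3 to 105 ± 21.6 (adjusted p = 0.00021). AT2G41480 rose 2.1-fold (adjusted p = 0.00073) and AT5G15180 rose 1.97-fold (adjusted p = 0.00058). As a set the list was higher (camera adjusted p = 0.00489), with adjusted p = 0.449 with an estimated correlation.

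Among the 10 largest falls of probe sets with 1 named gene, AT1G31910 fell 4.95-fold, from 773 ± 71.6 to 157 ± 32.1, and AT1G23440 fell 4.05-fold, from 188 ± 10.4 to 47 ± 10.8. Of probe sets without a gene name here, the 2 with the largest fitted falls, chosen after their values were seen, went from 57 ± 6.96 to 2.03 ± 1.55 (at least 2.61-fold lower, adjusted p = 4.7e-07) and from 177 ± 2.75 to 22.7 ± 4.11 (7.87-fold lower, adjusted p = 2.2e-08). No gene is assigned to them here, so it is not known whether either measures RSL4 itself. AT1G24040 was at least 2.56-fold lower. AT4G30320, a gene of the CAP family of secreted proteins, fell 3.44-fold. AT4G29780 fell 3.22-fold, AT5G24313 fell 3.16-fold, and ORA47, an ethylene response factor family gene, was at least 2.82-fold lower, a call that ended without rsl4-1 replicate 1 (adjusted p = 0.087). AT1G30990 was at least 1.25-fold lower. Its call ended without Col-0 replicate 1 or 2, rsl4-1 replicate 1 or 35S::RSL4 replicate 1 or 2 (adjusted p = 0.15, 0.13, 0.13, 0.07 and 0.071), and in a fit of only the 2 groups compared (adjusted p = 0.078). Among the 10 largest rises of probe sets with 1 named gene, AT4G33720, also of the CAP family, rose 10.4-fold, from 23.2 ± 2.12 to 241 ± 2.11, and AT1G23330 rose 2.86-fold. The 2 largest rises without a gene name here, likewise chosen afterwards, were 6.97-fold, from 126 ± 10.1 to 877 ± 45.9 (adjusted p = 9.4e-09), and at least 4.63-fold, from 15.7 ± 4.4 to 103 ± 5.32 (adjusted p = 4.8e-06). The second was too dim to be tested without rsl4-1 replicate 1 or 2. AT1G43040, AT1G28590, AT3G47250 and AT3G44070 were at least 2.33-fold, 1.72-fold, 1.7-fold and 1.58-fold higher. AT1G27570, AT3G15800 and AT1G10110 were at least 1.47-fold, 1.23-fold and 1.23-fold higher, and each of these 3 calls ended without Col-0 replicate 2 (adjusted p = 0.13, 0.06 and 0.29). That of AT3G15800 ended also without rsl4-1 replicate 1 or 2 (adjusted p = 0.078 and 0.061), and that of AT1G10110 without Col-0 replicate 1 (adjusted p = 0.086). With no filter on dim probe sets the calls of ORA47, AT1G30990, AT1G27570, AT3G15800 and AT1G10110 ended (adjusted p from 0.066 to 0.17), as did that of AT1G30990 with no intensity trend (adjusted p = 0.12). AT1G43040, AT1G28590, AT3G47250, AT3G44070, AT1G27570 and AT1G10110 were also too dim to be tested without rsl4-1 replicate 1 or 2. ORA47 was too dim to be tested without Col-0 replicate 1 or 2.

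In all, 236 probe sets were higher and 304 lower in rsl4-1 among 14170 tested with limma. Called genes were unevenly placed: 35 of 207 tested probe sets (16.9%) within 500 annotated loci of RSL4 were called, against 233 of 7420 elsewhere (3.14%; Fisher's exact test, two-sided, p = 3.68e-15). Within 250 loci the share was 9.91% of 111 (Fisher's exact test, two-sided, p = 0.00172). The stretch of 500 loci that holds RSL4 had 10.3% called, between stretches with 16.8% and 20.7%, and whether the share differed closest to RSL4 was not tested. Of the 10 genes with the largest rises 6 lay on chromosome 1 and 3 within those 500 loci, and of the 10 with the largest falls 7 and 4. Without these loci, an alternative chosen after seeing the data, 223 were higher and 282 lower. Only the 7627 tested probe sets with a known position could be left out, so any unplaced probe set near RSL4 stayed in these counts. Frequent calls also reached beyond 500 loci, so the counts do not show what remains without the whole region. Median centring gave 323 higher and 261 lower, or 55.3% higher against 43.7%. Leaving out Col-0 replicate 1 or 2 or rsl4-1 replicate 1 or 2 gave 100, 87, 60 or 81 higher and 152, 117, 162 or 155 lower.

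**Figure D1:**
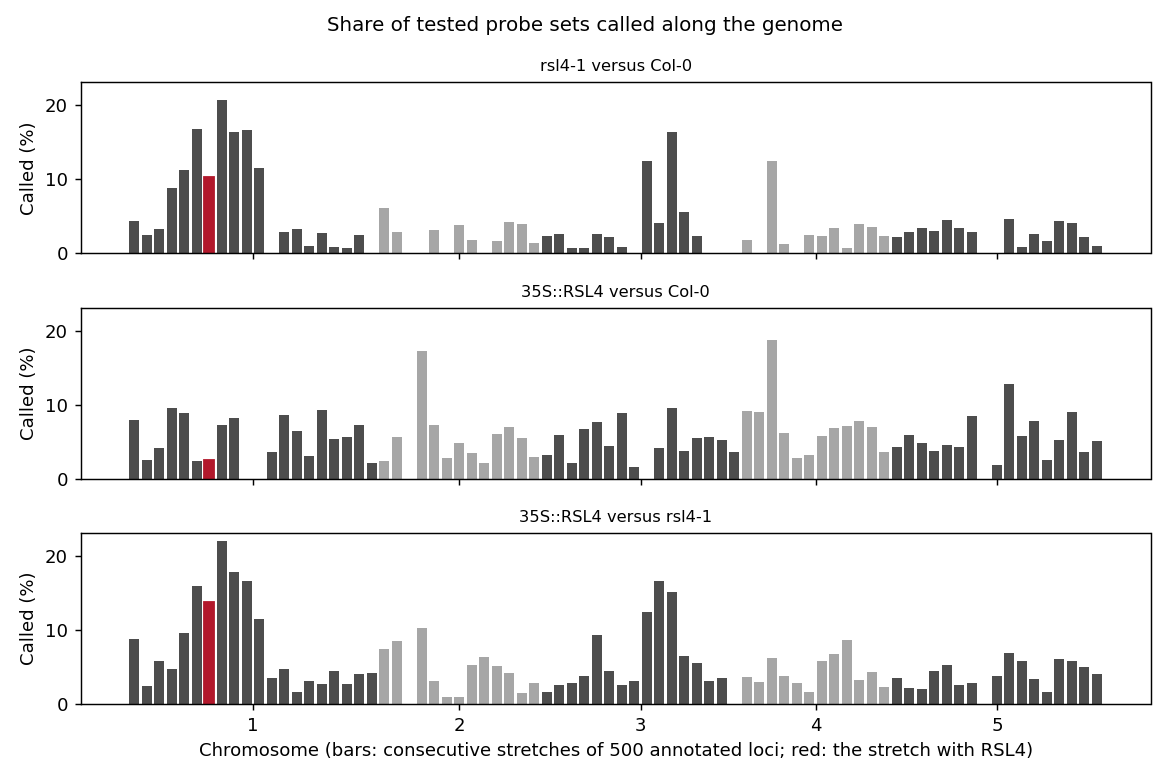
Bars give the percent of tested probe sets called in each stretch of 500 annotated loci, in order along chromosomes 1 to 5, for each of the 3 comparisons, with the stretch that holds RSL4 in red. Stretches of chromosome 1 reach 20.7% in rsl4-1 versus Col-0 and 22% in 35S::RSL4 versus rsl4-1.

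The comparison of 35S::RSL4 with Col-0 asked which root transcripts respond to more RSL4. The root hair cell wall genes EXPA7, EXPA18 and XTH26 and 11 of 18 measured class III peroxidases rose, and 1 peroxidase and the transcription factor genes STZ and ORA47 fell. Some of these moved the same way in rsl4-1, so their change need not be a response to more RSL4. There the peroxidases AT3G01190, AT5G15180 and AT5G39580 rose too (log2 changes 0.5, 0.98 and 0.73), and ORA47 fell (-1.68). EXPA7, EXPA18 and the peroxidases AT1G30870, AT1G34510 and AT5G19890 moved in opposite directions in the 2 lines. AT5G64120, a class III peroxidase, rose 4.13-fold, from 58.3 ± 8.53 to 239 ± 8.06 (log2 change 2.05, SE 0.16, adjusted p = 1.6e-06). XTH26 rose 2.85-fold, from 38 ± 3.67 to 108 ± 12.6 (adjusted p = 0.00018). STZ, a zinc finger repressor of stress responses and the annotated locus next to RSL4, fell 4.85-fold, from 296 ± 8.08 to 61 ± 0.707 (adjusted p = 2.1e-07). AT2G13870, annotated as a pseudogene, was at least 26.8-fold higher, with a signal of 600 ± 61 against 2.48 ± 2.66 (adjusted p = 1.6e-06). Its probe set is of a type that can bind several transcripts, so the signal may not come from this locus alone. It was too dim in the other genotypes to be tested without 35S::RSL4 replicate 1 or 2.

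All 3 measured root hair cell wall genes rose, and 3 of 3 did when adjusted over the list alone. EXPA7 rose 2.7-fold, from 107 ± 10.5 to 288 ± 18.5 (adjusted p = 4.3e-05), and EXPA18 rose 1.73-fold, from 260 ± 23.5 to 450 ± 20.6 (adjusted p = 0.0026). The list was higher as a set (camera adjusted p = 9.46e-08), with adjusted p = 0.0654 with an estimated correlation. Of the 7 extensins, 2 rose and 5 did not pass, and 5 were higher when adjusted over the list alone. AT4G08410 rose 1.58-fold (adjusted p = 0.012) and HRGP1 rose 1.4-fold (adjusted p = 0.035). Without Col-0 replicate 1 or 2 or 35S::RSL4 replicate 2 both calls ended (adjusted p = 0.13, 0.072 and 0.078 for AT4G08410, and 0.2, 0.15 and 0.19 for HRGP1). That of HRGP1 ended also with quantile normalization (adjusted p = 0.061), with no filter (adjusted p = 0.071) and with no intensity trend (adjusted p = 0.1). AT3G54580 and AT1G23720 had log2 changes of 0.55 (adjusted p = 0.065) and 0.48 (adjusted p = 0.076). The extensin set was higher (camera adjusted p = 0.000102), with adjusted p = 0.0654 with an estimated correlation.

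Of the 18 peroxidases, 11 rose, 1 fell and 6 did not pass, with the same counts of 11 and 1 adjusted over the list alone. AT1G34510 rose 2.75-fold, from 251 ± 12.3 to 696 ± 134 (adjusted p = 6.3e-05). AT4G26010 and AT5G17820 rose 1.97-fold and 1.94-fold (adjusted p = 0.00023 for each). AT5G19890 was the member that fell (log2 change -0.98, adjusted p = 0.0046). The list was higher as a set (camera adjusted p = 2.44e-11), with adjusted p = 0.0981 with an estimated correlation.

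JKD, a zinc finger gene of root patterning and the 1 measured member of the epidermal patterning list, fell 1.93-fold, from 49.5 ± 0.378 to 25.6 ± 0.967 (adjusted p = 0.0072), a call that ended without Col-0 replicate 1 or 2 or 35S::RSL4 replicate 2 (adjusted p = 0.076, 0.064 and 0.053). Among the other large falls, AT4G29780 fell 5.31-fold. AT4G27654 and AT5G17350 were at least 3.28-fold and 3.16-fold lower. ORA47 was at least 3.01-fold lower (adjusted p = 3.4e-06), AT5G47000 at least 2.75-fold lower, and EXLA3, an expansin-like gene, at least 2.67-fold lower. CML38, a calmodulin-like gene, was at least 1.41-fold lower, and AT4G27657 at least 1.18-fold lower. AT5G05250 was at least 1.96-fold lower, a call that ended without Col-0 replicate 2 or 35S::RSL4 replicate 2 (adjusted p = 0.16 and 0.17). Of probe sets without a gene name here, the 2 with the largest fitted falls, chosen after their values were seen, went from 48.6 ± 7.16 to 2.31 ± 1.5 and from 42.5 ± 8.17 to 4 ± 2.02 (at least 2.37-fold and 2.06-fold lower, adjusted p = 8.9e-05 and 2.9e-05), and the first was too dim to be tested without Col-0 replicate 1 or 2. The 2 with the largest rises went from 57 ± 6.96 to 396 ± 14.4 and from 15.7 ± 4.32 to 68.1 ± 6.48 (6.98-fold and at least 3.05-fold higher, adjusted p = 0.00027 and 6.2e-05). Among the other large rises, AT3G06460 was at least 3.97-fold higher, AT1G34330 rose 3.13-fold and AT3G49190 was at least 2.31-fold higher. AT5G19870, AT5G26080, AT4G33810 and AT5G43590 were at least 1.81-fold, 1.7-fold, 1.09-fold and 1.06-fold higher. The call of AT5G19870 ended without 35S::RSL4 replicate 2 (adjusted p = 0.05). Those of AT5G26080, AT4G33810 and AT5G43590 ended without Col-0 replicate 1 (adjusted p = 0.12, 0.076 and 0.13), and that of AT5G43590 also without Col-0 replicate 2 (adjusted p = 0.19). With no filter the calls of AT5G05250, AT5G26080, AT4G33810 and AT5G43590 ended (adjusted p from 0.065 to 0.14), as did that of AT5G05250 with no intensity trend (adjusted p = 0.057). AT3G49190, AT5G26080 and AT5G43590 were too dim to be tested without 35S::RSL4 replicate 1 or 2, and ORA47 and CML38 without Col-0 replicate 1 or 2. AT4G33810 was too dim to be tested without rsl4-1 replicate 1 or 35S::RSL4 replicate 2.

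In all, 480 probe sets were higher and 408 lower in 35S::RSL4 than in Col-0. Within 500 loci of RSL4, 8 of 207 tested probe sets were called (3.86%), against 416 of 7420 elsewhere (5.61%; Fisher's exact test, two-sided, p = 0.355). Median centring, which shifted this comparison by 0.11 on the log2 scale, gave 889 higher and 233 lower, or 79.2% higher against 54.1%. Leaving out Col-0 replicate 1 or 2 or 35S::RSL4 replicate 2 gave 126, 226 or 167 higher and 86, 144 or 167 lower, and leaving out 35S::RSL4 replicate 1 gave 262 lower.

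Both comparisons with Col-0 also had a lower signal of LHCB4.1, a light-harvesting protein gene from the list of shoot tissue markers. Its signal was 204 ± 21.9 in Col-0, 128 ± 11.9 in rsl4-1 (adjusted p = 0.016) and 125 ± 5.9 in 35S::RSL4 (adjusted p = 0.0093). The rsl4-1 call ended without Col-0 replicate 1 or 2 or rsl4-1 replicate 1 or 2 (adjusted p = 0.21, 0.058, 0.054 and 0.16) or with no intensity trend (adjusted p = 0.057). The 35S::RSL4 call ended without Col-0 replicate 1 or 35S::RSL4 replicate 2 (adjusted p = 0.16 and 0.07). RCA, the other measured shoot marker, had log2 changes of -0.22 (adjusted p = 0.54) and -0.23 (adjusted p = 0.39). The 6 rpl and 5 rps genes measured, which encode ribosomal proteins, were grouped by symbol after the data were seen. Symbols alone do not place each of them in the plastid genome. Of these genes rpl33 and rps4 were also lower in both lines. Their log2 changes were -1.50 and -0.76 in rsl4-1 (adjusted p = 0.006 and 0.014) and -1.21 and -1.0 in 35S::RSL4 (adjusted p = 0.019 and 0.0017), where rpl32 was lower too (log2 change -0.59, adjusted p = 0.038). The rpl genes were lower as a set in rsl4-1 (camera adjusted p = 0.00856), with adjusted p = 0.39 with an estimated correlation, and the rps genes in 35S::RSL4 (camera adjusted p = 0.0246), with adjusted p = 0.361 with an estimated correlation. In rsl4-1 the call of rps4 ended without Col-0 replicate 1 or 2 or rsl4-1 replicate 1 or 2 (adjusted p = 0.1, 0.12, 0.064 and 0.15). That of rpl33 ended without Col-0 replicate 2 or rsl4-1 replicate 2 (adjusted p = 0.07 and 0.097) and had adjusted p = 0.05 without Col-0 replicate 1. In 35S::RSL4 the call of rpl33 ended without Col-0 replicate 1 or 2 or 35S::RSL4 replicate 2 (adjusted p = 0.13, 0.11 and 0.18). That of rpl32 ended without Col-0 replicate 2, rsl4-1 replicate 1 or 2 or 35S::RSL4 replicate 1 or 2 (adjusted p = 0.33, 0.055, 0.056, 0.13 and 0.11) and with median centring (adjusted p = 0.077). The ratio of 3' to 5' GAPDH control signals, which rises as RNA degrades, was 1.65 and 1.65 on the Col-0 arrays. It was 1.09 and 1.35 on the rsl4-1 arrays and 1.25 and 0.833 on the 35S::RSL4 arrays. The first storage statement in the Col-0 labels gives 2 days of cold treatment of seeds and their growth text gives 4 days, while the labels of the other genotypes give 4 days in both, so this difference and genotype cannot be told apart.

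The comparison of 35S::RSL4 with rsl4-1 set the line named for added RSL4 against the mutant, although no probe set was identified here as that of RSL4. EXPA7, EXPA18, XTH26, 6 of 7 measured extensins and 7 of 18 measured peroxidases were higher in 35S::RSL4, and 3 peroxidases were lower. AT1G34510 was 6.63-fold higher in 35S::RSL4, at 696 ± 134 against 105 ± 21.6 (log2 change 2.73, SE 0.16, adjusted p = 2.3e-08). AT1G30870 and AT5G64120 were 5.45-fold and 5.46-fold higher (adjusted p = 2.8e-08 and 3.9e-08). AT4G33720 was at least 11.8-fold lower and hemb2 at least 12.6-fold lower than in rsl4-1 (adjusted p = 1.1e-08 and 4.9e-08).

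All 3 root hair cell wall genes were higher in 35S::RSL4 than in rsl4-1, as they were adjusted over the list alone: XTH26 4.44-fold, EXPA7 4.37-fold and EXPA18 2.63-fold. The list was higher as a set (camera adjusted p = 7.73e-11), with adjusted p = 0.0395 with an estimated correlation. Of the 7 extensins 6 were higher and 1 did not pass, and 7 were higher adjusted over the list alone. AT4G08410, AT5G06630, AT3G54580 and HRGP1 were 3.79-fold, 3.04-fold, 2.78-fold and 2.62-fold higher. The extensin set was higher (camera adjusted p = 2.93e-14), with adjusted p = 0.0162 with an estimated correlation. Of the 18 peroxidases 7 were higher, 3 lower and 8 did not pass, and 8 were higher and 5 lower adjusted over the list alone. AT5G19890 was 4.11-fold lower (adjusted p = 1.5e-06). The peroxidase set was higher (camera adjusted p = 0.000705), with adjusted p = 0.355 with an estimated correlation and 0.052 without 35S::RSL4 replicate 2.

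AT2G13870 was at least 27.5-fold higher in 35S::RSL4 than in rsl4-1, AT4G30320 was 6.84-fold higher and AT1G34330 at least 3.04-fold higher. AT2G03980 and AT5G26080 were at least 2.17-fold and 1.75-fold higher. AT1G30990 and the extensin AT1G26250, both within 500 loci of RSL4, were at least 1.69-fold and 1.06-fold higher. The first of these calls ended without 35S::RSL4 replicate 1 or 2 and the second without rsl4-1 replicate 1. JKD was 1.73-fold lower (adjusted p = 0.021), a call that ended without rsl4-1 replicate 1 or 2 or 35S::RSL4 replicate 1 or 2 (adjusted p = 0.063, 0.18, 0.073 and 0.091). With no filter the calls of AT1G30990, AT1G26250 and JKD ended (adjusted p = 0.085, 0.13 and 0.077), and with no intensity trend those of AT1G30990 and AT1G26250 (adjusted p = 0.058 and 0.072). AT4G27654 and AT1G43040 were at least 2.84-fold and 2.54-fold lower. AT1G28590, AT3G47250, AT3G44070, AT1G27570 and AT1G10110 were at least 1.88-fold, 1.86-fold, 1.73-fold, 1.6-fold and 1.35-fold lower. ORA47 had a log2 change of -2.29 (adjusted p = 0.00026) with a low signal in both genotypes, so no fold is given. The limits given above on testing dim probe sets with an array left out hold here too. AT1G26250 was likewise too dim to be tested without 35S::RSL4 replicate 1 or 2.

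In all, 452 probe sets were higher and 322 lower in 35S::RSL4 than in rsl4-1. Within 500 loci of RSL4, 39 of 207 were called (18.8%), against 350 of 7420 elsewhere (4.72%; Fisher's exact test, two-sided, p = 5.62e-13). Without these loci 428 were higher and 307 lower, with the same limits as for rsl4-1 versus Col-0. Median centring gave 585 higher and 242 lower, or 70.7% higher against 58.4%. Leaving out rsl4-1 replicate 2 or 35S::RSL4 replicate 1 or 2 gave 247, 274 or 279 higher, and leaving out rsl4-1 replicate 1 or 2 or 35S::RSL4 replicate 1 gave 160, 102 or 174 lower.

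Genes that fell in rsl4-1 and rose in 35S::RSL4 against the same Col-0 arrays were then counted, to find transcripts that differed from Col-0 in opposite directions in the 2 lines. They included EXPA7, the peroxidases AT1G34510 and AT1G30870, GSTU25, and the CAP family genes AT4G30320 and AT4G25790. Of the 10 named opposite changes, 5 lie on chromosome 1 in stretches of 500 loci where calls between rsl4-1 and Col-0 were frequent. The stretch of AT1G30870, which is 425 loci from RSL4, had 20.7% called (adjusted p = 9.29e-08), and that of AT1G34330 and AT1G34510, which are 915 and 941 loci from RSL4, had 16.4% (adjusted p = 0.000147). The stretches of GSTU25 and EXPA7 had 11.3% and 8.8% (adjusted p = 0.00165 and 0.0489). AT4G25790 had signals of 80.7 ± 2.77 in rsl4-1, 198 ± 12.2 in Col-0 and 414 ± 41.5 in 35S::RSL4. AT3G07070 had signals of 37.3 ± 4.43, 109 ± 5.23 and 168 ± 14, and AT5G40860 had 14.7 ± 0.28, 36.9 ± 3.75 and 71 ± 1.49. AT1G34330, annotated as a transcribed pseudogene, and AT2G03980 completed the 10 with the largest differences between 35S::RSL4 and rsl4-1 among probe sets with 1 named gene. Of probe sets without a gene name here, the 2 with the largest differences in the same directions, chosen after their values were seen, had signals of 2.03 ± 1.55, 57 ± 6.96 and 396 ± 14.4 and of 22.7 ± 4.11, 177 ± 2.75 and 407 ± 65.7 in rsl4-1, Col-0 and 35S::RSL4. They are the same 2 whose falls are given above for rsl4-1, and whether either measures RSL4 itself is not known here.

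**Figure D2:**
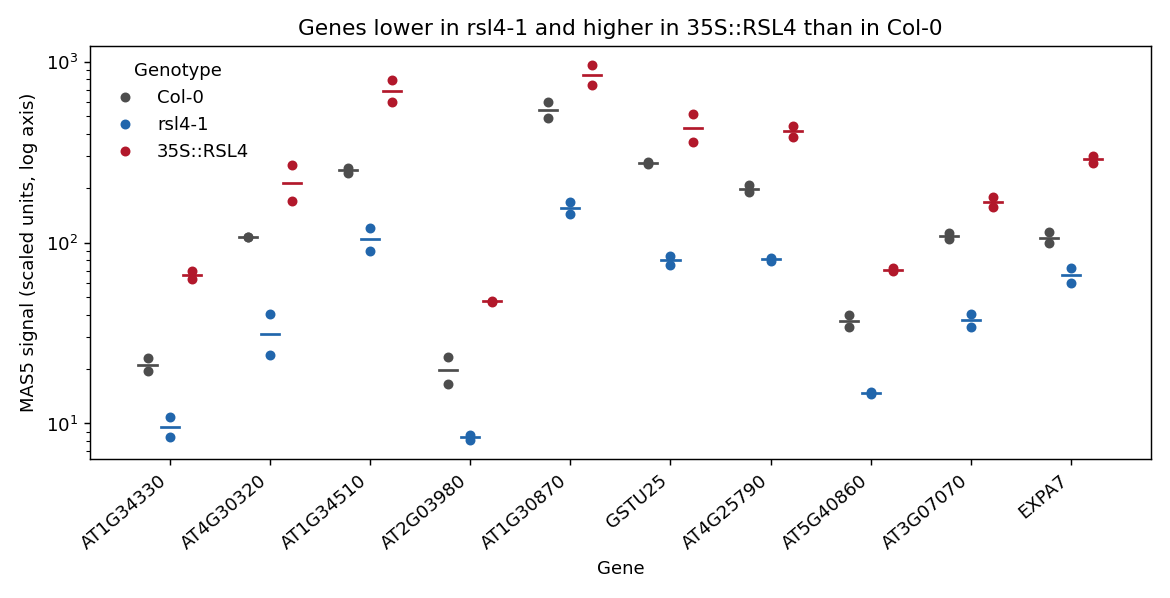
MAS5 signal on a log axis for the 10 named genes lower in rsl4-1 and higher in 35S::RSL4 than in Col-0, with a point per array (n = 2 per genotype) and a line at the geometric mean. The genes were chosen for this order of the genotypes, as in EXPA7, whose mean signals were 66.3, 107 and 288 in rsl4-1, Col-0 and 35S::RSL4.

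In all, 53 probe sets were lower in rsl4-1 and higher in 35S::RSL4. Independent lists gave 10.3 and simulated unchanged groups 0. The simulation drew all groups anew around the Col-0 means, so the Col-0 arrays themselves were not in it. The mirror class held 4, against 6.8 and 0, and its named member was the peroxidase AT5G19890. Another 63 were lower in both and 87 higher in both, against 8.75 and 7.99 for independent lists and 0.03 and 0.01 simulated. Without any simulated change a threshold of 0.05 calls hardly any probe set, so the simulated counts are no reference for overlaps of lists this long. Across probe sets, which are not independent, the log2 changes correlated at 0.336, and simulated unchanged groups gave 0.481 to 0.515. Unchanged groups of equal spread give about 0.5 whenever both changes share a control, so that range says nothing particular of these Col-0 arrays. The covariance of the log2 changes was 0.0398 against 0.0169 simulated, a difference of 0.0229. The 2 Col-0 arrays were not split between the comparisons, since each would have kept 1. Part of the same-direction excess may therefore come from the shared controls. The Col-0 samples also differed in the ratio of 3' to 5' GAPDH signals and in the labels' first cold treatment statement, as given above. Such a difference could move both other genotypes alike, and its share in the 63 and 87 was not tested. Leaving out Col-0 replicate 1 or 2, rsl4-1 replicate 2 or 35S::RSL4 replicate 2 gave 18, 24, 33 or 26 opposite changes. Among the named genes, the rise in 35S::RSL4 of AT4G30320, GSTU25, AT3G07070 and AT1G30870 was not called without Col-0 replicate 2 or 35S::RSL4 replicate 2 (adjusted p from 0.083 to 0.21). Without Col-0 replicate 1 that of AT4G30320, GSTU25, AT3G07070, AT5G40860 and AT2G03980 was not called (adjusted p from 0.12 to 0.22). Without 35S::RSL4 replicate 1 or 2 that of AT5G40860 and AT2G03980 was not called (adjusted p from 0.067 to 0.084), nor that of AT3G07070 without 35S::RSL4 replicate 1 (adjusted p = 0.058). The fall in rsl4-1 of AT1G34330 and AT2G03980 was not called without Col-0 replicate 2 (adjusted p = 0.15 and 0.24) or rsl4-1 replicate 2 (adjusted p = 0.1 and 0.061), nor that of AT2G03980 without rsl4-1 replicate 1 (adjusted p = 0.087), and the fall of EXPA7 was not called without Col-0 replicate 1 or 2 or rsl4-1 replicate 2 (adjusted p = 0.055, 0.21 and 0.18). With no filter a call against Col-0 ended for each named gene except EXPA7, AT1G34510 and AT4G25790 (adjusted p from 0.053 to 0.098). With no intensity trend a call ended for AT4G30320, GSTU25, AT3G07070, AT1G30870 and EXPA7 (adjusted p from 0.057 to 0.084), and in a fit of only the 2 groups compared for AT1G34330 and AT2G03980 (adjusted p = 0.068 and 0.069).

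**Figure D3:**
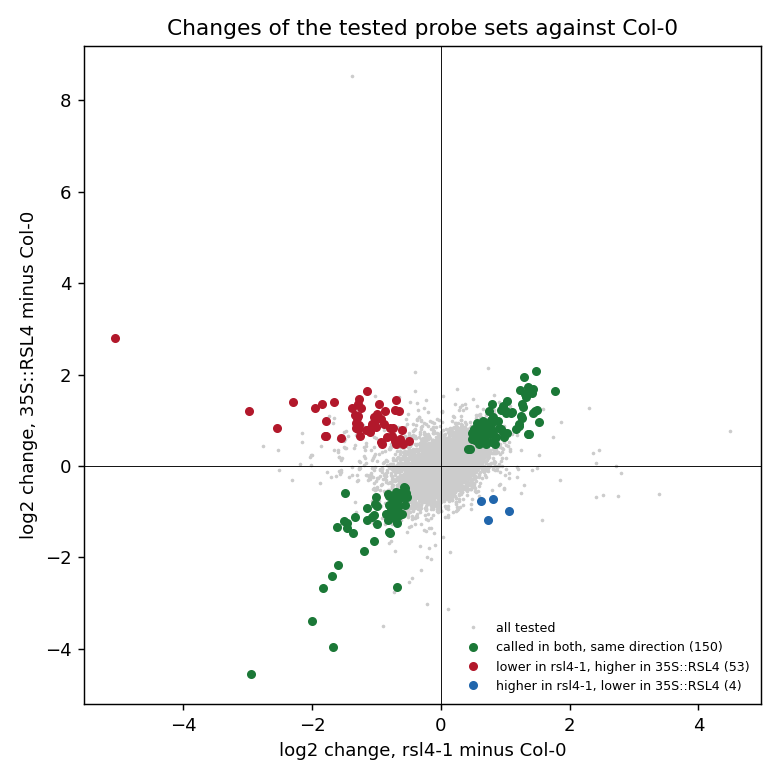
Each point is 1 of the 14170 tested probe sets, with its log2 change in rsl4-1 (horizontal) and in 35S::RSL4 (vertical) against Col-0. Colours mark the 53 lower in rsl4-1 and higher in 35S::RSL4, the 4 in the mirror class and those called in both with the same direction.

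The remaining lists had few measured members. FER and SCN1, a receptor kinase and a regulator of hair initiation, were the 2 measured members of the tip growth list. FER had log2 changes of 0.08 in rsl4-1 (adjusted p = 0.82) and 0.02 in 35S::RSL4 (adjusted p = 0.94) against Col-0, and SCN1 had 0.03 (adjusted p = 0.94) and 0.16 (adjusted p = 0.49). SGN3, AUR1 and GH3.5, the 1 measured member each of the endodermis, meristem and cell cycle, and auxin response lists, did not pass in any of the 3 comparisons, with log2 changes of -0.17, 0.13 and 0.10 in rsl4-1 and 0.05, -0.06 and 0.18 in 35S::RSL4 against Col-0. The reference genes TIP41, SAND and UBC21 did not pass in any comparison either, and their list had camera adjusted p of 0.756, 0.675 and 0.939. In 35S::RSL4 versus rsl4-1 the median of the reference genes was 0.07, their mean -0.04 and the direction of the test down. Of the 9 root hair bHLH regulators, 1 had a probe set and 0 were bright enough to test. The iron uptake and the defence and jasmonate lists likewise had 1 and 1 member with a probe set and 0 tested. The root hair specific, root cap, vascular, phosphate starvation, ethylene response, and heat and handling stress lists had 0 members with a probe set named in the annotation used here.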

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

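The comparison of control probe sets with Col-0, with its limit of 1.5-fold, was chosen only after the data were seen. Of the 64 control probe sets, which no comparison between genotypes used, 1 lay more than 1.5-fold above both Col-0 arrays on both arrays of a genotype. The probe set for the 5' end of actin had a mean signal of 105 ± 23 (SD, n = 2) in rsl4-1 against 50.9 ± 4.54 (n = 2) in Col-0, a ratio of 2.07. Both rsl4-1 arrays lay above both Col-0 arrays for 11 control probe sets and below for 7, and both 35S::RSL4 arrays for 13 and 13, where chance gives 16.7% each way. The ratio of 3' to 5' actin signals was 3.74 and 3.39 in Col-0, 2.31 and 2.70 in rsl4-1 and 2.94 and 2.43 in 35S::RSL4.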

How the results depend on the processing

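The alternative without loci near RSL4 was chosen only after the result was seen. The number of arrays and the noise of dim signals limit these results. Across the alternatives 70 counts stayed within 1.5 times the reported one and 41 moved further. Of list results 192 kept direction and side of the threshold, 8 were weaker and 4 reversed. Of these 192, 12 came from the mean of all probe sets of a locus. Each measured member had 1 probe set, so these could not differ. Of values for named genes 1312 were the same, 110 weaker, 4 stronger and 0 reversed. The arrays of called genes did not overlap between the genotypes compared, so leaving out an array could not reverse their direction. With no filter 107 probe sets were higher and 158 lower in rsl4-1 versus Col-0, 230 and 174 in 35S::RSL4 versus Col-0, 301 and 181 in 35S::RSL4 versus rsl4-1, and 26 changed in opposite directions. With no intensity trend 136 were higher in rsl4-1 and 282 in 35S::RSL4 than in Col-0, and in the upper part by mean signal 201 were lower in rsl4-1, where fewer probe sets were tested. A threshold of 0.1 gave 401 higher in rsl4-1 than in Col-0, 769 higher and 843 lower in 35S::RSL4 than in Col-0, and 599 lower in 35S::RSL4 than in rsl4-1. Median centring gave 889 higher and 233 lower in 35S::RSL4 than in Col-0. With the replicate block the counts were 230 and 290, 444 and 358, and 429 and 308, and the block changed no call of a named gene; the deviations of same-numbered arrays correlated at -0.189, 0.118 and -0.0849. Leaving out 1 array gave 60 (without rsl4-1 replicate 1) to 236 higher and 117 (without Col-0 replicate 2) to 287 lower in rsl4-1 versus Col-0. It gave 126 to 423 higher and 86 to 339 lower in 35S::RSL4 versus Col-0, both lowest without Col-0 replicate 1. It gave 247 to 392 higher and 102 to 261 lower in 35S::RSL4 versus rsl4-1, both lowest without rsl4-1 replicate 2, and 18 (without Col-0 replicate 1) to 41 opposite changes. With an estimated correlation adjusted p was 0.16 for root hair cell wall genes and 0.45 for peroxidases in rsl4-1 versus Col-0. It was 0.065 for root hair cell wall genes, 0.065 for extensins and 0.098 for peroxidases in 35S::RSL4 versus Col-0, and 0.36 for peroxidases in 35S::RSL4 versus rsl4-1. With fry it was 0.22 for peroxidases in rsl4-1. Peroxidases in 35S::RSL4 versus rsl4-1 had adjusted p from 2.2e-05 to 0.052 with 1 array left out, highest without 35S::RSL4 replicate 2. The reference genes, which passed nowhere, reversed in rsl4-1 versus Col-0 without rsl4-1 replicate 2 (adjusted p = 0.8, range 0.43 to 0.82). In 35S::RSL4 versus rsl4-1 they reversed with median centring (0.99) and without rsl4-1 replicate 1 (0.71) or 35S::RSL4 replicate 2 (0.88), with a range of 0.56 to 0.94. For the other changes the cause was not tested.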

Other observations

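The grouping of genes into families, the tests of the stretch around RSL4 other than the one of tandem copies, and the test of the Col-0 plants were chosen only after the result was seen. Of 31 families formed from the leading letters of gene symbols, 7 passed with camera in rsl4-1 versus Col-0 (adjusted p from 0.00527 to 0.0348): SWEET, XTH, PRA, SCPL, CYP and BGLU were higher and RPL lower. In 35S::RSL4 versus Col-0 7 passed (adjusted p from 5.16e-07 to 0.0246), with EXPA, PRA, XTH, SWEET, GH and BGLU higher and RPS lower, and in 35S::RSL4 versus rsl4-1 GSTU alone passed, higher (adjusted p = 0.0402). With an estimated correlation 0 passed in any comparison, with lowest adjusted p of 0.39, 0.361 and 0.856. Of the 7 measured SWEET sugar transporter genes, SWEET11 was higher in rsl4-1 (log2 change 1.16, adjusted p = 0.00021). SWEET2, SWEET16 and SWEET11 were higher in 35S::RSL4 than in Col-0, by 1.35, 0.83 and 0.80 (adjusted p = 0.00032, 0.014 and 0.0046). The call of SWEET16 ended without Col-0 replicate 1 or 35S::RSL4 replicate 1 or 2 (adjusted p = 0.17, 0.072 and 0.1), and that of SWEET11 in 35S::RSL4 without Col-0 replicate 2 (adjusted p = 0.077). These directions were the same under quantile normalization and median centring.

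Of the 7 measured expansins, 2 were higher and 2 lower in rsl4-1, and the difference between members was not tested. EXPA4 and EXPA15 had log2 changes of 0.83 (SE 0.12, adjusted p = 0.00053) and 0.75 (SE 0.13, adjusted p = 0.002) against Col-0, while EXPA7 and EXPA18, of the root hair list, had -0.69 and -0.60. In 35S::RSL4, 4 of the 7 measured expansins were higher than in Col-0: EXPA7 by 1.44, EXPA9 by 0.86, EXPA18 by 0.79 and EXPA4 by 0.48. The call of EXPA4 ended without Col-0 replicate 1 or 2 or 35S::RSL4 replicate 1 or 2 (adjusted p = 0.15, 0.13, 0.054 and 0.12). The calls of EXPA7 and EXPA18 in rsl4-1 ended without Col-0 replicate 1 (adjusted p = 0.055 and 0.22), Col-0 replicate 2 (0.21 and 0.071) or rsl4-1 replicate 2 (0.18 and 0.19), and that of EXPA18 without rsl4-1 replicate 1 (0.055). As a family the expansins were higher in 35S::RSL4 (camera adjusted p = 5.16e-07), with adjusted p = 0.361 with an estimated correlation. They did not pass as a family in rsl4-1 versus Col-0 (adjusted p = 0.125) or in 35S::RSL4 versus rsl4-1 (adjusted p = 0.133). The members' directions were the same under quantile normalization and median centring.

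Of the 7 measured xyloglucan endotransglucosylase genes, 3 were higher in rsl4-1 and 0 lower. XTH20, XTH18 and XTH19 had log2 changes of 1.01, 0.74 and 0.70 in rsl4-1 against Col-0 (adjusted p = 0.0033, 0.0041 and 0.0027), and XTH26, of the root hair list, had -0.64 and did not pass (adjusted p = 0.078). The difference between members was not tested. The call of XTH18 ended without Col-0 replicate 2 (adjusted p = 0.063) or rsl4-1 replicate 1 (adjusted p = 0.057), and XTH20 had adjusted p = 0.05 without rsl4-1 replicate 2. As a family of 7 they were higher in rsl4-1 (camera adjusted p = 0.00624), with adjusted p = 0.39 with an estimated correlation. They were also higher as a family in 35S::RSL4 than in Col-0 (camera adjusted p = 0.00848), with adjusted p = 0.361 with an estimated correlation. There 2 were higher and 0 lower: XTH26 by 1.51 and XTH19 by 0.48 (adjusted p = 0.00018 and 0.029), and the call of XTH19 ended without Col-0 replicate 1 or 2 or 35S::RSL4 replicate 1 or 2 (adjusted p = 0.22, 0.11, 0.11 and 0.061). Between 35S::RSL4 and rsl4-1 the family did not pass (camera adjusted p = 0.794), with 1 member higher and 1 lower. The directions of both family medians against Col-0, and of the members named for each line, were the same under quantile normalization and median centring.

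Calls between rsl4-1 and Col-0 were frequent on the part of chromosome 1 that holds RSL4, with an odds ratio of 6.27 (95% interval 4.13 to 9.31) within 500 loci, 6.01 (4.36 to 8.19) within 1000 and a lower 3.11 (1.48 to 5.89) within 250, a difference that was not tested. Tandem copies that share one signal were argued against as the whole cause, since merging called loci within 3 loci of each other left an odds ratio of 5.39 (3.4 to 8.28). A stretch around RSL4 in the rsl4-1 line that differs from Col-0 is a candidate explanation: within 500 loci the odds ratio was 4.69 (3.17 to 6.8) in 35S::RSL4 versus rsl4-1, which uses the same rsl4-1 arrays, and 0.677 (0.286 to 1.37) in 35S::RSL4 versus Col-0. With rsl4-1 replicate 2 alone against Col-0 and replicate 1 alone against 35S::RSL4, which compare no array in common, the odds ratios were 6.9 (3.85 to 11.8) and 6.01 (3.56 to 9.71), and with the replicates exchanged 7.57 (4.4 to 12.5) and 4.62 (2.9 to 7.13), so rsl4-1 stood apart there, as it would also if genes that respond to RSL4 happened to lie there. Such genes stay open. At an unadjusted p under 0.05, 35S::RSL4 moved 5.71% of the 35 called probe sets near RSL4 the opposite way and 14.6% of 233 elsewhere (Fisher's exact test, two-sided, p = 0.19). In either direction it moved 22.9% and 60.1% (Fisher's exact test, two-sided, p = 4.13e-05). Most of those moves, 6 near RSL4 and 106 elsewhere, were in the same direction as in rsl4-1, and both changes share the Col-0 arrays. The count in either direction therefore cannot decide on genes that respond to RSL4. Nor do these counts exclude genes that need RSL4 without responding to more of it.

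Of 78 stretches of 500 loci, 7 passed in rsl4-1 versus Col-0, 6 on chromosome 1 and 1 on chromosome 3. In 35S::RSL4 versus rsl4-1, 5 passed, 4 on chromosome 1 and 1 on chromosome 3, and in 35S::RSL4 versus Col-0 0 did. The stretch on chromosome 3, from AT3G44070 to AT3G47210, was the same in both, with 16.4% and 15.1% called (adjusted p = 0.000147 and 0.0168), against 9.59% in 35S::RSL4 versus Col-0 (adjusted p = 0.856), and no explanation of it was tested.

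Probe sets lower in 35S::RSL4 than in Col-0 numbered 408, of which 117 were also lower than in rsl4-1 and 63 also lower in rsl4-1 than in Col-0. A condition of the Col-0 plants alone, such as the seed treatment stated differently in their labels, could lower both other genotypes alike. Among 169 probe sets chosen with 35S::RSL4 replicate 1, replicate 2 lay below the rsl4-1 mean by a median log2 difference of -0.447 (87% below 0), and with the replicates exchanged by -0.292 (81.1% of 265), which argues against such a condition as the whole cause. It stays open as a part of the pattern, and both choices used the same Col-0 and rsl4-1 arrays.

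AT2G13870 was high in 35S::RSL4 only among the 3 genotypes, with a signal of 600 ± 61 (SD, n = 2). A 35S promoter inserted nearby might raise neighbouring genes too, but of 2 other measured loci within 20 loci 0 were called higher, AT2G13970 with a log2 change of -0.04 and AT2G13840 with -0.40. These are too few to decide. Binding of a transcript of the construct by this probe set, which is of a type that can bind several transcripts, was not tested.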
